A study of Mus musculus with 2 samples.

How the data were processed

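Endothelial cells sorted from mouse ileum were profiled as 2 droplet-based 3' single-cell RNA libraries, which carry the same labels and form 1 group (n = 2). Per the submitters' processing notes, bcl2fastq 2.2 and Cell Ranger 3.1.0 were used with the mouse build mm10; the gene annotation is not given in the sources used here. The values deposited by the authors are raw counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library with 31053 gene rows. The matrices hold called cells, 1026 barcodes in library 1 and 6302 in library 2. No deposited cell annotation was used here, and the labels do not say which cells came from which sort gate, so all cell classes were rebuilt. Gene coordinates were taken from GENCODE vM21 on GRCm38 by Ensembl gene ID, and 11471 of 11481 IDs tested matched (99.9%).

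Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept, 978 and 6067. Scrublet, run per library in scanpy, called 4 cells (0.409%) of library 1 and 5 (0.0824%) of library 2, which were removed. With so few calls the caller was taken not to have worked in library 2, unless doublets had been removed before deposit, which the sources used here do not say, so a run without the highest 5% of doublet scores in each library was added. The 974 and 6062 cells left had medians of 3368.5 and 3811.5 UMIs, 1701 and 1792.5 genes, and 2.49 and 2.95% mitochondrial UMIs. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used.

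Clusters were named from marker genes written down before the data were examined; the scoring limits were set afterwards. A cluster was called LEC-like or BEC-like where its lymphatic and blood endothelial markers differed by at least 3 on the log2 scale, and another cell type where that type's markers led by at least 2. For LEC-like, BEC-like and BEC subset names, at least 3 markers had to be detected at 20 CPM (UMI counts normalised to the class total). Other cell types needed at least 3 markers with a UMI in at least 25% of the cluster's cells. BEC-like cells were clustered again and called arterial-like, capillary-like or venous-like where markers led by at least 1 on the log2 scale. Clusters led by markers of another class among their top 10 genes stayed unnamed or were called mixed, and 4 cells of library 2 with over 1% haemoglobin UMIs were left out of naming. Clusters of BEC-like cells with median UMIs far below the library median and no own marker among the top 10 genes also stayed without a subset name.

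Since clustering and testing on the same genes would inflate differences, genes were split into 2 sets of 15530 and 15523 rows by a hash of the gene ID. Cells were clustered on each set, and each gene was tested in the classes made from the clustering on the other set. Clusters were named with the same markers and the leading genes of all rows in both cases. Genes expressed together can fall in both sets, so the split need not remove all of this inflation. Naming markers and sort gate genes were not tested. Both clusterings gave the same name to 6697 of the 6698 cells that each called LEC-like or BEC-like, and the same BEC subset to 5404 of 5610 (96.3%). The shared naming by itself raises this agreement. Shares of classes use the clustering on all variable genes.

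UMIs were summed per library and class for classes with at least 20 cells in both libraries. Sums were tested with edgeR's quasi-likelihood test (robust), TMM scaling, edgeR's expression filter with a minimum count of 10, and the library as a block, because the classes of a library come from the same sample. P-values were adjusted by the Benjamini-Hochberg method with a false discovery rate of 0.05. LEC-like and BEC-like cells were fitted as 4 sums (1 residual degree of freedom), and the 3 BEC subsets together as 6 sums (2 residual degrees of freedom). The median prior degrees of freedom over genes were infinite in the first fit and in that of the capillary kinds, and 33 in the BEC subsets, so p-values rest mainly on a spread shared across genes. Levels are CPM as mean ± SD over the 2 libraries, and log2 fold changes are fitted values ± SE. The SE was derived from the test, as the absolute log2 fold change divided by the square root of the F value. It rests mainly on the shared spread and can understate the counting error of genes near 0 in 1 class. Changes per library were computed on CPM plus 1. The fold of a gene with 0 UMIs in a class is a lower bound against 3 counts over the class. Near-identical gene copies share reads, so values of Ccl21a, Hspa1a, Ly6, Gbp and H2 family genes are uncertain.

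Named genes followed a rule fixed in advance: per comparison, the 12 largest increases and the 12 largest decreases among passing genes of at least 50 CPM in the higher class of both libraries and the same direction in both, and up to 4 members of each of 21 gene lists. The lists covered signalling, immune, transport, metabolic, matrix and tissue-handling genes. Each was counted over all genes and adjusted over the list alone, and tested with limma's camera with a preset correlation of 0.01 and with an estimated one. No list passed with an estimated correlation in any comparison. That form of the test uses the residual degrees of freedom of the fit, 1 or 2 here. It had almost no power at that number, so its adjusted p says little for or against a list.

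The testing steps were tested on simulated counts with known changes. The changed genes were drawn from well-expressed genes, and their share was far smaller than the share called in the data. Counts were drawn with the spread estimated by the same fit. The shares below therefore do not test the classes, that spread, weakly expressed genes or scaling where many genes change. For LEC-like against BEC-like cells (10837 genes), 87% of 2-fold and 100% of 4-fold changes were recovered, and 4.12% of calls were false. For arterial-like against capillary-like cells (10472 genes) the shares were 83 and 100%, with 3.68% false. For the comparison of capillary kinds (10653 genes) they were 100 and 100%, with 6.10% false. Shares of cells carry 95% Clopper-Pearson intervals and summed counts of a single library 95% Poisson intervals, both covering counting error only.

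Alternatives fixed before the data were examined were DESeq2 with its size factors, no scaling, no expression filter, no library block, classes from all variable genes, each library clustered on its own, Leiden resolutions of 0.5 and 2, filters of 200 genes with 25% and 1000 genes with 10% mitochondrial UMIs, doublets kept, equal cell numbers in both libraries, and each library alone. Removal of the highest doublet scores, a minimum of 2000 UMIs per cell, removal of LEC-like clusters led by mitochondrial genes, removal of cells that all variable genes named neither LEC-like nor BEC-like, the comparison of 2 capillary kinds and removal of capillary-like clusters led by the gene of the other kind were added after the data had been seen. Versions were Python packages numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.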

Results

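The data were 2 single-cell RNA libraries of endothelial cells sorted from the ileum, the last part of the small intestine, of wild-type male C57Bl/6 mice aged 8 weeks. The sort removed cells carrying the epithelial protein EpCAM or the leukocyte protein CD45 and kept CD31-positive cells. PDPN then separated blood endothelial cells (BECs, PDPN-negative) from lymphatic endothelial cells (LECs, PDPN-positive). Both libraries carry the same labels, so they form 1 group with n = 2, and every comparison is between cell classes found in both. The labels do not say whether the libraries came from separate mice, so the p-values need not reflect differences between mice. They rest on how class differences vary between these 2 libraries, a spread estimated mainly across genes, which may be technical. The labels do not tie a cell to a sort gate either. Classes were therefore rebuilt from marker genes fixed before the data were examined, and the ending "-like" marks such a class. Library 1 held 1026 barcodes and 3806199 unique molecular identifiers (UMIs), and library 2 held 6302 barcodes and 26645476 UMIs. After filtering, 974 and 6062 cells were analysed, with medians of 3368.5 and 3811.5 UMIs per cell.

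Most cells were BEC-like, and most of these were capillary-like. BEC-like cells made up 90.3% of library 1 (880 of 974 cells, 95% Clopper-Pearson interval 88.3 to 92.1%) and 79.2% of library 2 (4801 of 6062, 78.2 to 80.2%). LEC-like cells made up 8.21% (80 cells, 6.57 to 10.1%) and 16.5% (1003 cells, 15.6 to 17.5%). Capillary-like BECs were 67.6% of library 1 (64.5 to 70.5%) and 62.7% of library 2 (61.5 to 63.9%). Arterial-like BECs were 9.86% (8.06 to 11.9%) and 8.56% (7.87 to 9.29%), and venous-like BECs 11.2% (9.28 to 13.3%) and 6.76% (6.14 to 7.42%). The sort gates can set the LEC and BEC shares, the filter on cells moved them (11.8% LEC-like in library 2 with at least 1000 genes and at most 10% mitochondrial UMIs), and the intervals cover counting error only. Some clusters of these classes had genes outside the markers among their 10 leading genes. These were immediate early genes such as Egr1 and Fos in part of the capillary-like cells. In both venous-like clusters they were the adhesion genes Icam1 and Madcam1, with Sele in 1 of them, beside venous markers such as Selp and Ackr1. Mitochondrial genes led a LEC-like cluster of 11 cells in library 1 and 338 in library 2 (median 1322 UMIs over both), the interferon response genes Gbp4 and Gbp2 another of 20 and 234 cells, and Egr1 and Junb another of 9 and 100 cells. A further 17 and 71 BEC-like cells fitted no subset and stayed unnamed.

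**Figure D1:**
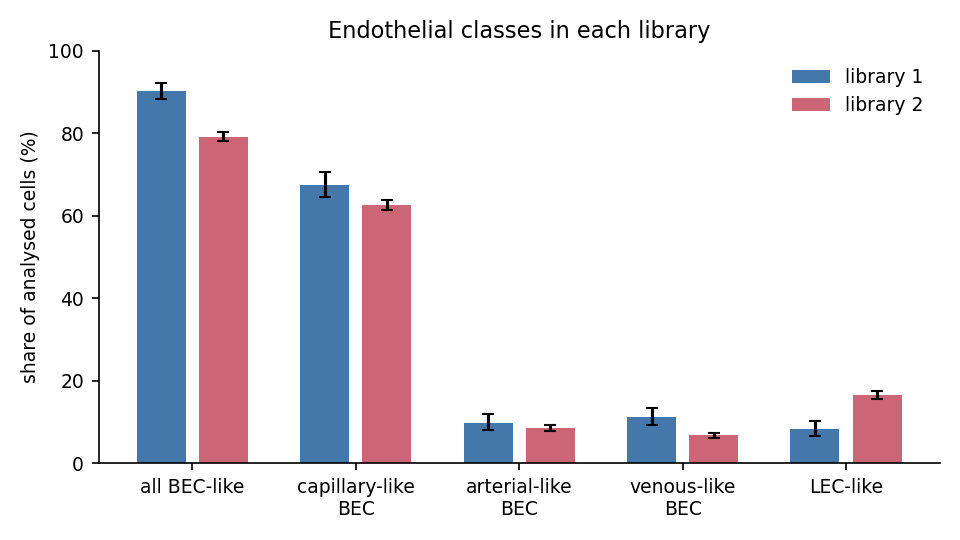
Share of analysed cells (%, y axis) in each endothelial class (x axis) for library 1 and library 2; bars are shares, error bars are 95% Clopper-Pearson intervals, and the capillary-like, arterial-like and venous-like bars are parts of the BEC-like bar. LEC-like cells were 8.21% of library 1 and 16.5% of library 2.

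Among the genes behind the sort gates, Pdpn stood at 284 CPM (UMI counts normalised to the class total) in the LEC-like cells of library 1 (95% Poisson interval 223 to 357) and 366 CPM in those of library 2 (343 to 390). BEC-like cells held 0 Pdpn UMIs in library 1, with a 95% Poisson upper limit of 1.11 CPM, and 0.658 CPM in library 2 (0.360 to 1.10). Pecam1, which encodes CD31, stood at 560.1 and 584 CPM in LEC-like cells and at 1398 and 1320.0 CPM in BEC-like cells. Epcam and Ptprc, the gene of CD45, reached at most 0.783 CPM in either class. Pdpn was also 1 of the 6 markers that named LEC-like cells, so its level is no check of that name, and neither gate genes nor naming markers were tested between the classes.

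The first comparison asked how the lymphatic and blood endothelial cells of the ileum, the populations named in the sort, differ in expression. Wnt2, a Wnt ligand, stood at 150.1 ± 25.3 CPM in LEC-like cells and 0.118 ± 0.166 CPM in BEC-like cells (mean ± SD, n = 2 libraries), a log2 fold change of 9.42 ± 0.33 (SE). Rspo3, which amplifies Wnt signalling, stood at 271 ± 7.90 against 0.553 ± 0.350 CPM (log2 8.39 ± 0.26). The lymphocyte survival cytokine Il7 (150.3 ± 18.5 against 1.30 ± 0.720 CPM, log2 7.08 ± 0.28) and the alarmin Il33 (424 ± 32.7 against 7.74 ± 1.15 CPM, log2 5.71 ± 0.19) were higher too, as were the transcription factor genes Maf (1543 ± 43.0 against 5.13 ± 1.21 CPM) and Tbx1 (343 ± 45.1 against 1.68 ± 1.52 CPM). BEC-like cells held more of the chemokine Cxcl12 (2816 ± 136 against 83.3 ± 24.3 CPM, log2 -5.02 ± 0.17), the fatty acid binding protein Fabp4 (7687 ± 1294 against 519 ± 222 CPM, log2 -3.98 ± 0.14), Ly6a (log2 -5.62 ± 0.18) and the secretoglobin Scgb3a1 (1147 ± 325 against 18.1 ± 14.6 CPM, log2 -5.81 ± 0.20). On GRCm38 (mm10, GENCODE vM21), Wnt2 (ENSMUSG00000010797) lies on chromosome 6 from 17988940 to 18030585 on the minus strand, Rspo3 (ENSMUSG00000019880) on chromosome 10 from 29452416 to 29535867 on the minus strand, and Il7 on chromosome 3 from 7569994 to 7613760 on the minus strand.

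Of 10990 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5291 passed a false discovery rate of 0.05. Of these, 2506 were higher and 2785 lower in LEC-like cells, and 97.1% had the same direction in both libraries, against 77.0% of all genes tested. Here and below the passing genes were picked on these same libraries, which by itself raises that share. The adjusted p of that test was 2.20e-166 for Wnt2, 1.68e-209 for Rspo3 and 1.97e-191 for Cxcl12. The median prior degrees of freedom over genes were infinite, so for most genes the spread came from a trend shared across genes, and the size of such p-values says little about each gene's own replicates. The SE values were derived from the same test, so for genes near 0 in 1 class, such as Wnt2, they can understate the counting error. Other genes with large positive changes were Sema3d (log2 8.94 ± 0.26) and Sema3a (log2 7.72 ± 0.32), which encode secreted guidance cues, Thy1 (log2 8.58 ± 0.22) and Pgf, placental growth factor (log2 5.45 ± 0.26). Large negative changes included the nucleotide-hydrolysing enzyme Entpd1 (log2 -5.46 ± 0.26), the efflux transporter Abcb1a (log2 -5.08 ± 0.25) and the E-selectin gene Sele (log2 -5.95 ± 0.37). The BEC-like sums are mostly capillary-like cells, so a change need not hold in each subset. Sele was high in venous-like BECs and near 0 in the arterial-like and capillary-like ones, as given below. LEC-like cells also carried fewer UMIs and a higher mitochondrial share. Median UMIs were 2843 against 3381 in library 1 and 2132 against 4048 in library 2, and median mitochondrial shares were 3.47 against 2.36% and 5.35 against 2.62%.

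**Figure D2:**
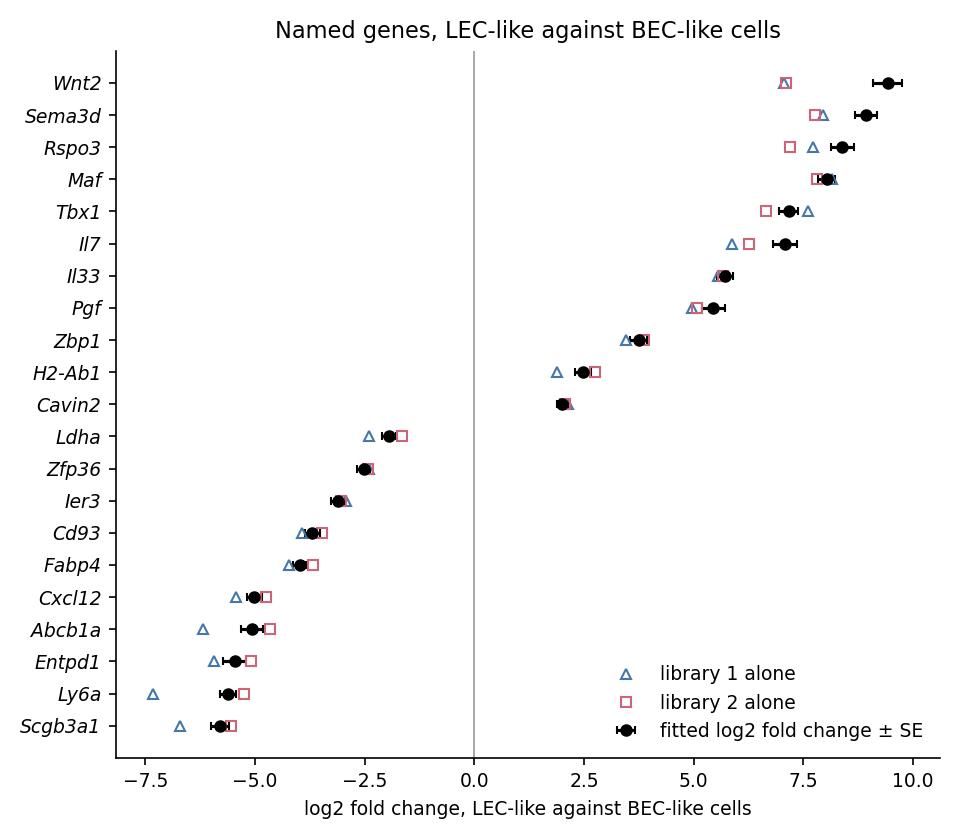
Log2 fold change between LEC-like and BEC-like cells (x axis) for 21 named genes (y axis); black points are fitted values with SE bars over both libraries, and open symbols are each library alone, computed on CPM plus 1, which shrinks the change of genes near 0 in either class. Maf reached 8.03 ± 0.19 and Ly6a -5.62 ± 0.18, and both libraries lie on the same side of 0 for every gene drawn.

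Antigen presentation genes of MHC class II were higher in LEC-like cells. All 6 tested members rose, also when adjusted over the list alone, among them H2-Ab1 (125 ± 11.6 against 24.8 ± 8.49 CPM, log2 2.48 ± 0.19) and H2-DMa (22.3 ± 1.54 against 4.53 ± 1.71 CPM). The list passed limma's camera with a preset correlation of 0.01 (adjusted p = 0.00312) but not otherwise (adjusted p = 0.83 with an estimated correlation). The estimated form had 1 residual degree of freedom in this comparison and could hardly pass any list. Of 12 MHC class I genes, 6 rose, 2 fell and 4 did not pass, the same numbers as over the list alone, with Psmb9 up by log2 0.98 ± 0.15 and H2-Q4 at log2 -1.66 ± 0.15. Among 24 interferon response genes, 11 rose and 6 fell (12 and 6 adjusted over the list alone), with Zbp1 (log2 3.74 ± 0.19) and Gbp2 (log2 1.77 ± 0.16) up and Ly6a down. Neither list passed camera. In library 2, genes of other cell types differed too. LEC-like cells held the immunoglobulin gene Igkc at 58.4 CPM (95% Poisson interval 49.4 to 68.5) against 27.4 CPM (25.2 to 29.7), and the epithelial gene Reg3b at 19.98 CPM (14.9 to 26.3) against 6.95 CPM (5.88 to 8.17). They held less of the pericyte gene Rgs5 (1.96 against 14.8 CPM) and of the haemoglobin gene Hbb-bs (2.35 against 538 CPM). Among BEC subsets of library 2, Hbb-bs stood at 377 CPM in capillary-like, 0.851 in arterial-like and 2.32 CPM in venous-like cells. In library 1 it stood at 0 CPM in LEC-like and 0.904 CPM in BEC-like cells. The 4 cells of library 2 with over 1% haemoglobin UMIs were left out of naming but not of the sums. Library 1 held 1 UMI of Igkc in each class and 0 of Reg3b. The B-lineage cells described below were led by Igkc and by MHC class II genes. RNA of such cells as a source of part of the MHC class II change was not tested. The median log2 fold change of the MHC class II list was 1.87 in library 1 and 2.36 in library 2.

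Dissociation and immediate early genes, which respond to tissue handling, were lower in LEC-like cells, the class with fewer UMIs and more mitochondrial reads. Of 20 members, 18 fell and none rose, also when adjusted over the list alone, with a median log2 fold change of -1.95. Ier3 stood at 198 ± 6.18 against 1569 ± 47.6 CPM (log2 -3.11 ± 0.15), Zfp36 at 301 ± 2.03 against 1615 ± 33.0 CPM and Socs3 at 137 ± 61.5 against 1330.4 ± 6.36 CPM. Camera with the preset correlation gave an adjusted p of 1.48e-12 (adjusted p = 0.83 with an estimated correlation). Glycolysis genes also fell, 8 of 14 over all genes and over the list alone, led by Ldha (log2 -1.95 ± 0.16) and Pfkp (log2 -1.50 ± 0.20), with a camera adjusted p of 0.0242 (adjusted p = 0.83 with an estimated correlation). Of 21 nuclear genes of oxidative phosphorylation, 2 rose, 3 fell and 16 did not pass.

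Solute transporters were mostly lower in LEC-like cells. Of 16 solute and amino acid transporters, 11 fell and 2 rose (11 and 3 adjusted over the list alone), including the water and glycerol channel Aqp7 (log2 -5.25 ± 0.33) and Abcb1a, with a camera adjusted p of 0.00455 (adjusted p = 0.83 with an estimated correlation). Of 21 lipid handling genes, 9 fell, 4 rose and 8 did not pass, the same as over the list alone, and those that fell included the HDL receptor Scarb1 (log2 -4.21 ± 0.20) and Tcf15 (log2 -4.05 ± 0.22). The lipid list had a camera adjusted p of 0.0363 (adjusted p = 0.83 with an estimated correlation). Among 10 chemokines and atypical chemokine receptors, 7 fell and 2 rose, also over the list alone, with a camera adjusted p of 0.029 (adjusted p = 0.83 with an estimated correlation). Caveolae and transcytosis genes went both ways, with 5 up, 5 down and 3 not passing (6 and 5 adjusted over the list alone), Cavin2 at log2 2.01 ± 0.13 and Ehd4 at log2 -2.85 ± 0.16.

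Among 8 Wnt, R-spondin and BMP signals, 5 rose and 2 fell, and among 16 leukocyte adhesion genes 6 rose and 9 fell, with the mannose receptor Mrc1 up (log2 8.22 ± 0.31). Of 14 Notch pathway genes 9 fell and 3 rose, with Notch2 up (log2 4.63 ± 0.35). Of 19 genes of the VEGF, angiopoietin and apelin axis 13 fell and 5 rose, and of 26 endothelial transcription factors 9 fell and 10 rose. Junction genes gave 7 lower and 2 higher of 10, with Cd93 at log2 -3.69 ± 0.17. Matrix genes gave 12 lower and 10 higher of 24. Vasoactive genes gave 10 lower and 4 higher of 14. All these counts were the same when adjusted over the list alone. Coagulation genes gave 7 higher and 5 lower of 14 (7 and 6 adjusted over the list alone), with Serping1 up (log2 2.81 ± 0.17). Axon guidance genes gave 4 higher and 9 lower of 16 (5 and 9). Of 16 immune regulators and cytokines 5 rose and 7 fell (6 and 7). None of these lists passed camera, and median, mean and camera did not share a sign for immune regulators, coagulation genes and transcription factors. DESeq2 called 2434 genes and equal numbers of cells per class in both libraries 2972, against 5291. Without scaling the split was 2904 higher and 2448 lower, so the majority turned, and the median of all genes moved by 0.10 log2.

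The second comparison set arterial-like against capillary-like BECs. Jag1, a Notch ligand, stood at 562 ± 43.5 against 93.4 ± 9.55 CPM (mean ± SD, n = 2, log2 2.67 ± 0.12, SE), Vegfc, a growth factor for lymphatic vessels, at 309 ± 37.5 against 21.9 ± 8.72 CPM (log2 3.78 ± 0.14), and the vasoconstrictor gene Edn1 at 554 ± 21.9 against 105 ± 17.4 CPM (log2 2.43 ± 0.13). Plat, tissue plasminogen activator, reached 1057 ± 52.0 against 199 ± 16.4 CPM (log2 2.48 ± 0.12) and fibronectin, Fn1, 493 ± 93.6 against 33.7 ± 5.93 CPM (log2 3.95 ± 0.17). Capillary-like cells held more of the HDL receptor Scarb1 (606 ± 157 against 119 ± 22.0 CPM, log2 -2.07 ± 0.14), the transcription factor genes Tshz2 (254 ± 90.1 against 42.0 ± 10.9 CPM) and Meox2 (127 ± 28.5 against 19.3 ± 4.25 CPM), and Nrp2, a VEGF and semaphorin co-receptor (227 ± 11.8 against 47.7 ± 5.88 CPM, log2 -2.07 ± 0.15). For Meox2 the higher level came from capillary-like clusters with more Gpihbp1 than Plvap, described below. The other capillary-like cells, the larger part, lay below the arterial-like level of Meox2. Changes against capillary-like cells, here and in the third comparison, were not tested against each of these kinds and need not hold for both. Vegfc (ENSMUSG00000031520) lies on chromosome 8 from 54077606 to 54187096 on the plus strand of GRCm38.

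Of 10583 genes tested, 1493 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 838 higher and 655 lower in arterial-like cells (720 and 761 without scaling, so the majority turned), and 99.1% had the same direction in both libraries, against 64.1% of all genes tested. The adjusted p was 1.80e-19 for Jag1 and 1.26e-12 for Scarb1. The largest increases included S100a4 (log2 6.75 ± 0.25), the potassium channel subunit Kcne3 (log2 6.59 ± 0.29), Enpp6 (log2 5.65 ± 0.20) and the Wnt inhibitor Dkk2 (log2 4.37 ± 0.18). The largest decreases included the organic anion transporter gene Slco2b1 (log2 -3.73 ± 0.28). Median UMIs of arterial-like and capillary-like cells were 3312.5 against 3328.5 and 4116 against 3926, and median mitochondrial shares 2.57 against 2.19% and 2.81 against 2.46%.

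Lipid handling genes were lower in arterial-like cells than in the pooled capillary-like cells: 11 of 23 fell and 2 rose (13 and 2 adjusted over the list alone), with Scarb1 and Abcg1 (log2 -1.57 ± 0.21) among them and a camera adjusted p of 2.98e-08 (adjusted p = 0.427 with an estimated correlation). Lipid handling genes also differed between the capillary kinds described below, so this need not hold against each kind. Of 20 genes of the VEGF, angiopoietin and apelin axis 9 fell and 3 rose (9 and 4), with a camera adjusted p of 0.0141 (adjusted p = 0.48 with an estimated correlation). Solute transporters gave 5 lower and 2 higher of 16 (7 and 3), including the lactate transporter Slc16a1 (log2 -2.37 ± 0.26), with a camera adjusted p of 0.00704 (adjusted p = 0.48 with an estimated correlation). Interferon response genes gave 6 lower and none higher of 24 (6 and 2 over the list alone), including Rsad2 (log2 -1.35 ± 0.18) and Irf8 (log2 -0.87 ± 0.15), with a camera adjusted p of 0.00704 (adjusted p = 0.427 with an estimated correlation).

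Notch pathway genes gave 5 higher and 1 lower of 13 (6 and 1 over the list alone), with Jag1 up and a camera adjusted p of 0.0166 (adjusted p = 0.427 with an estimated correlation). Coagulation genes gave 5 higher and 2 lower of 12, as over the list alone (camera adjusted p = 0.00418, adjusted p = 0.427 with an estimated correlation). Vasoactive genes gave 6 higher and 4 lower of 13, as over the list alone (camera adjusted p = 0.00704, adjusted p = 0.427 with an estimated correlation). Dissociation and immediate early genes were higher in 12 of 20 and lower in none (14 over the list alone), with Atf3 at log2 0.92 ± 0.10 and Nr4a1 at log2 0.85 ± 0.11 (camera adjusted p = 3.74e-06, adjusted p = 0.48 with an estimated correlation). Matrix genes split into 8 higher and 10 lower of 23 (11 and 10 over the list alone), with Fn1, Col18a1 (log2 4.97 ± 0.28) and Fbn1 (log2 2.07 ± 0.15) up. DESeq2 called 753 genes, the fit without the library block 891, and equal numbers of cells 936. Median, mean and camera did not share a sign for junction and axon guidance genes.

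The third comparison set venous-like against capillary-like BECs. Venous-like cells were higher in most tested genes of the leukocyte adhesion, chemokine and antigen presentation lists, counted below. None of these lists passed camera with an estimated correlation, a form that had only 2 residual degrees of freedom here and so little power. Sele, encoding E-selectin, stood at 650.3 ± 133 against 0.735 ± 1.04 CPM (mean ± SD, n = 2, log2 9.28 ± 0.21, SE), Icam1 at 2997 ± 352 against 281 ± 33.8 CPM (log2 3.54 ± 0.13), and Madcam1, the vessel adhesion molecule that gut-homing lymphocytes bind, at 1507 ± 119 against 6.86 ± 5.47 CPM (log2 7.53 ± 0.43). The chemokine Cxcl10 reached 436 ± 9.33 against 9.44 ± 3.56 CPM (log2 5.93 ± 0.16) and Cd74, the MHC class II invariant chain, changed by 3.92 ± 0.13 on the log2 scale. Capillary-like cells held more of the Notch ligand Dll4 (328 ± 0.226 against 32.9 ± 13.4 CPM, log2 -2.96 ± 0.16), its receptor Notch4 (124 ± 14.5 against 10.1 ± 4.67 CPM), and the endothelin receptor Ednrb (log2 -4.29 ± 0.26). Madcam1 lies on chromosome 10 from 79664559 to 79668537 and Sele (ENSMUSG00000026582) on chromosome 1 from 164048234 to 164057677, both on the plus strand of GRCm38.

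Of 10583 genes, 2954 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1581 higher and 1373 lower in venous-like cells, and 98.1% had the same direction in both libraries, against 69.6% of all genes tested. Without scaling between the sums the split was 1168 higher and 2020 lower, and the median of all genes moved by -0.15 log2. Changes here are relative to the scaled fit. The adjusted p was 1.53e-26 for Sele and 8.85e-18 for Dll4. Further increases were Adgrg6 (log2 9.29 ± 0.20), Vcam1 (log2 6.09 ± 0.53), the nitric oxide sensor subunit Gucy1a1 (log2 7.29 ± 0.19) and the tight junction gene Cldn5 (log2 2.40 ± 0.11). Il33 reached 44.6 ± 3.87 against 0.827 ± 1.17 CPM. Il6 reached 347 ± 32.2 against 81.7 ± 18.5 CPM (log2 2.22 ± 0.12), a call lost when each library was clustered on its own. Venous-like cells carried more UMIs than capillary-like cells (medians 4350 against 3328.5 and 6159 against 3926) and a higher median mitochondrial share (4.05 against 2.19% and 3.98 against 2.46%).

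All 6 MHC class II genes rose, also over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.313 with an estimated correlation), with H2-Aa at log2 3.22 ± 0.24. Of 12 MHC class I genes 9 rose and none fell (11 over the list alone), with Tap1 at log2 1.01 ± 0.12 (camera adjusted p = 0.00017, adjusted p = 0.313 with an estimated correlation). Interferon response genes gave 14 higher and 3 lower of 24 (16 and 3), with Gbp2 up (log2 1.75 ± 0.12) and Rsad2 down (log2 -3.37 ± 0.23) (camera adjusted p = 1.15e-05, adjusted p = 0.313 with an estimated correlation). Leukocyte adhesion genes gave 9 higher and 2 lower of 14, as over the list alone (camera adjusted p = 0.00017, adjusted p = 0.313 with an estimated correlation). Chemokines and their receptors gave 6 higher and none lower of 9 (6 and 1 over the list alone), including Cxcl9 (log2 3.35 ± 0.22) and Cxcl1 (log2 2.02 ± 0.16) (camera adjusted p = 0.00373, adjusted p = 0.509 with an estimated correlation). Immune regulators and cytokines gave 10 higher and 5 lower of 15, as over the list alone (camera adjusted p = 0.00373, adjusted p = 0.345 with an estimated correlation).

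Coagulation genes gave 8 higher and 2 lower of 12 (8 and 3 over the list alone), with the complement inhibitor Serping1 (log2 4.67 ± 0.17) and the protein C receptor Procr (log2 4.21 ± 0.28) up and Plat down (log2 -2.07 ± 0.15) (camera adjusted p = 0.00942, adjusted p = 0.313 with an estimated correlation). Notch pathway genes gave 7 lower and 2 higher of 13 (8 and 3), camera adjusted p = 0.00335 (adjusted p = 0.321 with an estimated correlation). Matrix genes gave 13 lower and 3 higher of 23 (14 and 3), with Timp2 up (log2 4.22 ± 0.24) (camera adjusted p = 0.00017, adjusted p = 0.313 with an estimated correlation). The pericyte gene Rgs5 was lower in venous-like cells too, at 1.85 against 24.6 CPM in library 1 and 7.34 against 13.8 CPM in library 2. RNA of pericytes as a source of part of the matrix change was not tested. Lipid handling genes gave 10 lower and 3 higher of 23 (10 and 4), with Tcf15 down (log2 -2.59 ± 0.17) (camera adjusted p = 0.0133, adjusted p = 0.313 with an estimated correlation). As in the second comparison, the lipid change need not hold against each capillary kind. Axon guidance genes gave 8 lower and 3 higher of 14 (8 and 4), with Sema7a down (log2 -3.66 ± 0.17) (camera adjusted p = 0.0402, adjusted p = 0.509 with an estimated correlation). Dissociation and immediate early genes went both ways, 6 higher and 5 lower of 20 (7 and 7), with Ier3 up (log2 1.05 ± 0.09). DESeq2 called 1531 genes, the fit without the library block 1877, and equal numbers of cells 1926. Median, mean and camera did not share a sign for junction, caveolae, oxidative phosphorylation and dissociation genes.

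**Figure D3:**
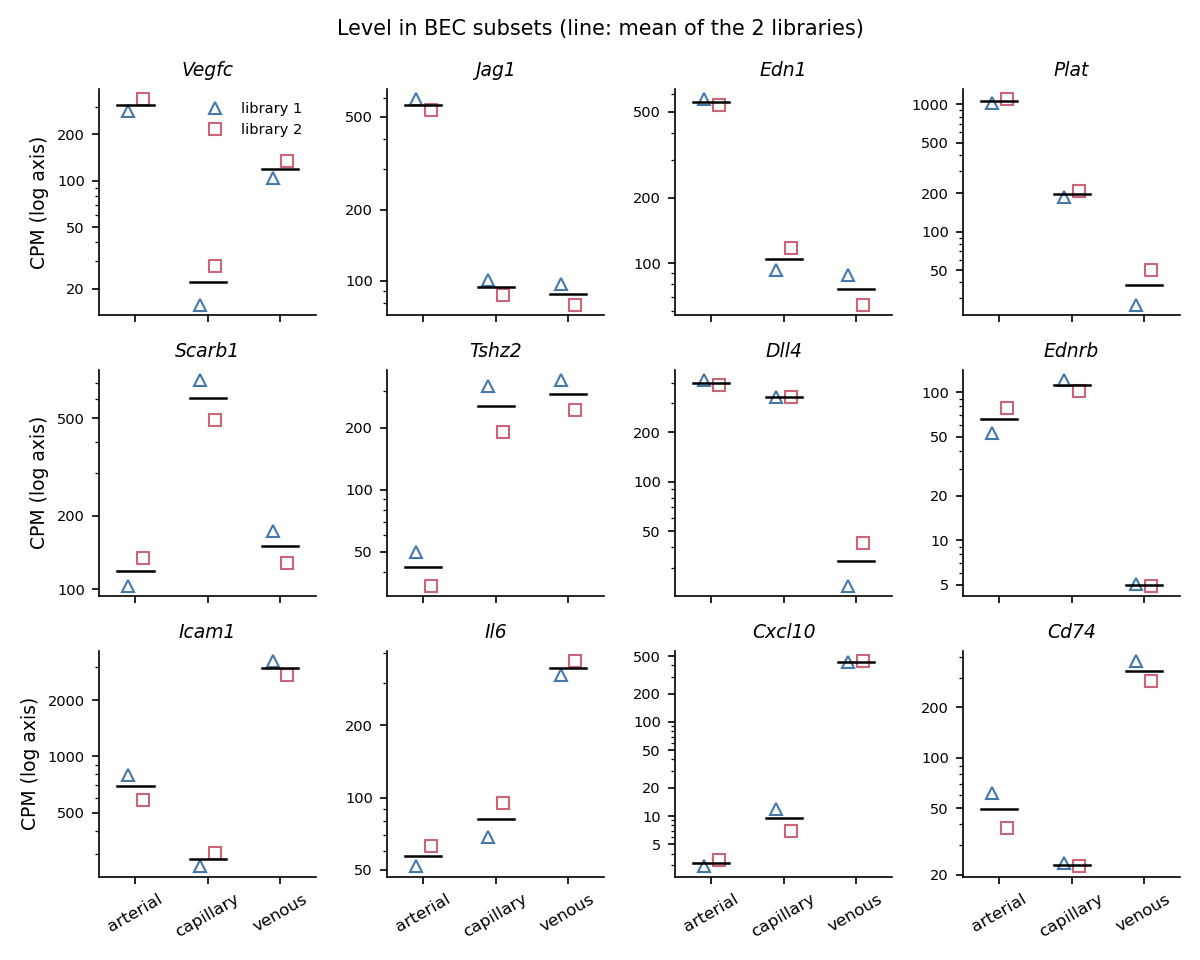
Level of 12 named genes (CPM, log y axis) in arterial-like, capillary-like and venous-like BECs (x axis); triangles are library 1, squares library 2 and lines the mean of both. Vegfc, Jag1, Edn1 and Plat lie highest in arterial-like cells, Icam1, Il6, Cxcl10 and Cd74 in venous-like cells, with Cxcl10 at 436 ± 9.33 CPM (mean ± SD, n = 2) in the latter.

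The fourth comparison set arterial-like against venous-like BECs. The Notch genes Dll4 (399 ± 20.6 against 32.9 ± 13.4 CPM, mean ± SD, n = 2, log2 3.30 ± 0.16, SE), Notch4 (155 ± 3.61 against 10.1 ± 4.67 CPM) and Jag1 (562 ± 43.5 against 88.0 ± 12.8 CPM) were higher in arterial-like cells, as were Plat (1057 ± 52.0 against 38.3 ± 16.2 CPM, log2 4.55 ± 0.15) and the phosphatase Alpl (230.0 ± 28.5 against 2.52 ± 1.19 CPM). Venous-like cells held more Sele (650.3 ± 133 against 1.93 ± 2.73 CPM, log2 -7.85 ± 0.27), Madcam1 (1507 ± 119 against 4.35 ± 6.15 CPM), Cxcl10 (436 ± 9.33 against 3.15 ± 0.325 CPM), histidine decarboxylase, Hdc (553 ± 153 against 1.90 ± 2.68 CPM, log2 -7.26 ± 0.25), and the prostaglandin synthase Ptgs1 (332 ± 5.78 against 12.4 ± 7.27 CPM). Several genes had 0 UMIs in 1 of the classes in both libraries, so their folds are lower bounds against 3 counts over the class. Nebl was at least 131-fold higher in arterial-like cells, and Cadm3 at least 181-fold, coagulation factor F5 at least 122-fold and Masp1 at least 56.0-fold higher in venous-like cells. The call for F5 was lost under DESeq2.

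Of 10583 genes, 2457 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1222 higher and 1235 lower in arterial-like cells (1408 and 1043 without scaling), and 97.8% had the same direction in both libraries, against 65.8% of all genes tested. The adjusted p was 2.76e-18 for Dll4 and 2.23e-21 for Sele. Arterial-like cells carried fewer UMIs than venous-like cells (medians 3312.5 against 4350 and 4116 against 6159) and a lower median mitochondrial share (2.57 against 4.05% and 2.81 against 3.98%). Notch pathway genes gave 8 higher and 1 lower of 13 (9 and 2 over the list alone; camera adjusted p = 2.54e-05, adjusted p = 0.348 with an estimated correlation). Matrix genes gave 14 higher and 2 lower of 23 (15 and 3), including Lama3 (log2 2.61 ± 0.17), camera adjusted p = 1.18e-06 (adjusted p = 0.348 with an estimated correlation). Dissociation and immediate early genes gave 10 higher and 2 lower of 20 (12 and 3), with Ier3 down (log2 -1.11 ± 0.10), camera adjusted p = 0.00442 (adjusted p = 0.61 with an estimated correlation).

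Many antigen presentation and immune genes were lower in arterial-like cells, though no list passed camera with an estimated correlation. That form had only 2 residual degrees of freedom here and so little power. All 6 MHC class II genes fell, as over the list alone (camera adjusted p = 1.53e-05, adjusted p = 0.484 with an estimated correlation). Of 12 MHC class I genes 10 fell (11 over the list alone), with H2-K1 at log2 -0.74 ± 0.09 (camera adjusted p = 1.18e-06, adjusted p = 0.348 with an estimated correlation). Of 24 interferon response genes 16 fell and 2 rose, as over the list alone, with Ifit1 at log2 -2.35 ± 0.18 (camera adjusted p = 9.5e-08, adjusted p = 0.348 with an estimated correlation). Leukocyte adhesion genes gave 7 lower and 3 higher of 14 (8 and 3; camera adjusted p = 0.00442, adjusted p = 0.348 with an estimated correlation). Chemokines and their receptors gave 5 lower and 1 higher of 9 (6 and 1; camera adjusted p = 0.0126, adjusted p = 0.61 with an estimated correlation). Immune regulators gave 10 lower and 2 higher of 15 (10 and 4), with Il6 at log2 -2.69 ± 0.15 (camera adjusted p = 0.000392, adjusted p = 0.348 with an estimated correlation). DESeq2 called 1351 genes, the fit without the library block 1598, and equal numbers of cells 1498. Median, mean and camera did not share a sign for Wnt, R-spondin and BMP signals and for transcription factors.

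The 2 libraries gave close profiles within each class. Across genes at a mean of at least 10 CPM, Pearson's r of log2 CPM between libraries was 0.921 in LEC-like cells, 0.976 in BEC-like cells, 0.932 in arterial-like, 0.974 in capillary-like and 0.947 in venous-like cells. The log2 fold changes of the libraries correlated across genes at 0.860 for LEC-like against BEC-like cells, 0.646 for arterial-like against capillary-like, 0.818 for venous-like against capillary-like and 0.703 for arterial-like against venous-like cells. Genes are not independent replicates, so no p-value is given. LEC subsets were not compared: clustered on either gene set, only 1 LEC-like cluster held at least 20 cells in both libraries.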

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

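The test of free LEC RNA and the use of doublet scores below were chosen after the results were seen. With 2 libraries, no library could be tested as standing apart from the rest. The cells described here were named neither LEC-like nor BEC-like on all variable genes, and groups are described where they held more than the 3 cells that a count of 0 allows (0.308% in library 1 and 0.0495% in library 2). The intervals of both groups so described for library 1 reach below that share.

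The CD45-negative gate should remove leukocytes, yet T or NK-like cells numbered 4 in library 1 (0.411%, 95% Clopper-Pearson interval 0.112 to 1.05%) and 19 in library 2 (0.313%, 0.189 to 0.489%). A cluster of 35 cells in library 2 (0.577%, 0.402 to 0.802%), with 3 cells in library 1 (0.308%, 0.0636 to 0.897%), was named plasma-like by the fixed markers but was led by Cd74, Igkc, H2-Aa and Cd79a, genes shared with B cells, so only its B lineage is clear. Pericyte or smooth muscle-like cells, led by Rgs5 and Notch3, numbered 6 in library 1 (0.616%, 0.226 to 1.34%) and 55 in library 2 (0.907%, 0.684 to 1.18%). Fibroblast-like cells, led by Dcn and Col3a1, numbered 1 in library 1 (0.103%, 0.00260 to 0.571%) and 55 in library 2 (0.907%, 0.684 to 1.18%). Epithelial-like cells, which the EpCAM-negative gate should remove, numbered 0 in library 1 and 11 in library 2 (0.181%, 0.0906 to 0.324%). They were led by Reg3b and Krt8 and had a median of 42724 UMIs, far above the 4048 of BEC-like cells. None of the 11 was among the highest 5% of doublet scores, and they held Pecam1 at 4.70 CPM (95% Poisson interval 0.569 to 17.0), but their origin was not tested.

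In library 2, 83 cells (1.37%, 95% interval 1.09 to 1.69%) carried both LEC and BEC markers, and library 1 held 0 such cells. Free RNA of LECs at an even rate in all cells is argued against as the whole source. The test used 281 LEC genes outside the naming markers. These genes were picked in these same libraries, as passing genes at least 4 higher on the log2 scale in LEC-like than in BEC-like cells. Of the 83 mixed cells, 80 (96.4%, 89.8 to 99.2%) held more of these UMIs than a rate shared by mixed and BEC-like cells allows (Poisson, Bonferroni adjustment). The same held for 44 of 4801 BEC-like cells. The mixed cells held a median of 74 such UMIs where that rate gave 4.12. They were set apart by clustering that used LEC genes, so some excess follows from the choice. The adjustment covers all pooled cells and so allows for the choice of cells, but not for the choice of genes. Free RNA reaching cells unevenly was not tested. Droplets holding 1 LEC and 1 BEC cannot be told apart from another origin: 2 genes lay above 2 times both parents, within the highest count of 7 among 20 sets of simulated pairs, but the median of 4200 UMIs lay below every simulated median (6127 to 7755), and while 79 of the 83 were among the highest 5% of doublet scores (175 of 4801 BEC-like and 9 of 1003 LEC-like cells), that score measures likeness to such pairs whatever the origin. The mixed cells held Lyve1 at 39.5% and Mmrn1 at 43.0% of the LEC-like level, and Flt1 at 0.639 and Plvap at 0.454 times the BEC-like level. The design has 1 group, so no biological explanation was tested.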

How the results depend on the processing

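The runs without the highest doublet scores, with at least 2000 UMIs per cell, without clusters led by mitochondrial genes or by the gene of the other capillary kind, and without cells named neither LEC-like nor BEC-like, and every test of capillary kinds, were chosen after the results were seen. DESeq2 called 2434 genes for LEC-like against BEC-like cells, 753 for arterial-like against capillary-like, 1531 for venous-like against capillary-like, 1351 for arterial-like against venous-like and 1205 for the capillary kinds; the cause was not tested. Equal numbers of cells per class gave 2972, 936, 1926, 1498 and 2246 in the same order, with fewer cells and so fewer counts by construction. Without the replicate block, which pairs classes of the same library, the 3 comparisons of BEC subsets gave 891, 1877 and 1598 and the capillary kinds 1700; the cause was not tested. On the single gene sets used for testing, 39 and 16 of the 83 mixed cells and 0 and 1 pericyte-like cell of library 2 fell in the LEC-like or BEC-like sums, and without them 5363, 1488, 2962, 2462 and 3530 genes passed. The remaining alternatives kept each count within 1.5 times, and no gene called both ways changed sign in the 4 planned comparisons. For the capillary kinds 3 such genes did with classes from all variable genes, with each library clustered on its own, at resolution 0.5, with doublets kept and without the highest doublet scores, and 4 under the stricter filter.

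Shares of these classes in library 2 moved beyond their intervals under 4 settings; cells were named anew under each, and the cause was not tested. At least 1000 genes and at most 10% mitochondrial UMIs gave 11.8% LEC-like, 84.0% BEC-like, 9.36% arterial-like, 66.7% capillary-like and 8.01% venous-like cells. At least 200 genes and at most 25% gave 78.1% BEC-like, 7.41% arterial-like and 7.55% venous-like cells. With doublets kept, 7.73% were venous-like, and without the highest doublet scores 64.9% were capillary-like. Plvap-high cells moved to 44.1% and Gpihbp1-high cells to 22.6% under the stricter filter, and Plvap-high cells to 43.3% without the highest doublet scores, where 0 of 5781 cells were mixed. Leiden resolution 0.5 gave 1.02% mixed cells. The stricter filter gave 0 T or NK-like and 0 epithelial-like cells but named 3 (0.364%) and 17 (0.320%) cells B cell-like, a name absent from all other settings, and whether cells changed name was not tested; library 1 clustered on its own gave 0 T or NK-like, plasma-like, fibroblast-like and pericyte-like cells.

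Among named genes, 7230 values kept direction and call and 234 lost the call. Of values of a single library, 493 stayed within 1 SD, 479 moved by more and 2 changed sign. Without replicate 2, Bmp4 stood at 0.31 for arterial-like against venous-like cells (-2.03 without replicate 1, log2 -1.49 ± 0.38 with both libraries) and Madcam1 at -1.54 for Plvap-high against Gpihbp1-high capillary-like cells (1.73 without replicate 1, 1.71 ± 0.36 with both); the cause was not tested. A single library leaves no residual degrees of freedom, so counts of calls have no such value. Library 1 limits the depth, with 80 LEC-like, 96 arterial-like and 109 venous-like cells.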

Other observations

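The comparison of capillary kinds with its alternatives, the run on cells of at least 2000 UMIs and the test of scaling were chosen after the results were seen. Capillary-like clusters were split by whether their summed UMIs held more Plvap or more Gpihbp1, into Plvap-high cells (383 in library 1, 39.3% of all cells, and 2526 in library 2, 41.7%) and Gpihbp1-high cells (275, 28.2%, and 1275, 21.0%). The Plvap-high class includes a cluster of 8 and 45 cells led by Btnl9 and Gpihbp1 and another of 1 and 28 cells led by Aqp1 and Gpihbp1, so its name holds for the class and not for each cluster. Plvap forms the diaphragms of fenestrae, and Gpihbp1 carries lipoprotein lipase to the capillary lumen. Of 10712 genes tested, 3527 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1843 higher and 1684 lower in Plvap-high cells, and 96.9% had the same direction in both libraries, against 68.5% of all genes tested. Without the clusters led by the gene of the other kind 3341 passed, of which 3327 were among the 3527. Without scaling the split was 1354 higher and 2534 lower and the median of all genes moved by -0.14 log2. Gpihbp1-high cells held more of the water channel Aqp1 (4368 ± 1038 against 179.7 ± 19.3 CPM, mean ± SD, n = 2, log2 -4.43 ± 0.11, SE), lipoprotein lipase, Lpl (416 ± 129 against 7.18 ± 0.313 CPM), the transcription factor gene Meox2 (358 ± 41.7 against 4.41 ± 0.462 CPM) and the tight junction gene Cldn5 (1023 ± 332 against 13.1 ± 6.05 CPM, log2 -5.68 ± 0.14). Plvap-high cells held more of the collagen Col15a1 (703 ± 76.9 against 73.6 ± 20.2 CPM, log2 3.26 ± 0.12), Col13a1 (363 ± 32.0 against 7.77 ± 1.07 CPM) and Esm1 (314 ± 14.3 against 34.7 ± 8.73 CPM, log2 3.43 ± 0.14). They also carried more UMIs (medians 3725 against 2941 and 4275 against 3313) and a higher median mitochondrial share (2.45 against 1.80% and 2.68 against 1.97%).

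By list, junction genes gave 7 lower and 1 higher of 11 in Plvap-high cells, as adjusted over the list alone (limma's camera adjusted p = 0.000286, adjusted p = 0.632 with an estimated correlation). Lipid handling genes gave 11 lower and 5 higher of 21, as over the list alone (camera adjusted p = 0.0153, adjusted p = 0.632 with an estimated correlation). Interferon response genes gave 13 lower and 5 higher of 24 (13 and 6) (camera adjusted p = 0.0389, adjusted p = 0.632 with an estimated correlation). Coagulation genes gave 10 higher and 1 lower of 13 (11 and 1; camera adjusted p = 0.000284, adjusted p = 0.632 with an estimated correlation). Dissociation and immediate early genes gave 12 higher and 1 lower of 20 (13 and 2; camera adjusted p = 0.000284, adjusted p = 0.632 with an estimated correlation). Glycolysis genes gave 8 higher and none lower of 14, as over the list alone, with Ldha at log2 0.85 ± 0.11 (camera adjusted p = 0.00455, adjusted p = 0.632 with an estimated correlation). Immune regulators gave 9 higher and 2 lower of 14, as over the list alone (camera adjusted p = 0.0217, adjusted p = 0.632 with an estimated correlation). Median, mean and camera did not share a sign for Wnt, R-spondin and BMP signals, Notch pathway genes and solute transporters.

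No LEC-like or BEC-like cell had UMIs of 3 or more of 6 proliferation markers. A count of 0 allows up to 3.75% and 0.341% such cells in library 1 and 0.299% and 0.0625% in library 2, which limits cells with these UMIs detected, not cycling cells.

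LEC-like cells of library 2 held fewer UMIs than BEC-like cells, with a ratio of medians of 0.527 (95% bootstrap interval 0.499 to 0.555). Damaged LECs with a high mitochondrial share could give this, and a cluster led by mitochondrial genes, with a median of 1322 UMIs over both libraries, held 338 of the 1003 LEC-like cells of library 2 and 11 of the 80 of library 1. Among cells of at most 5% mitochondrial UMIs the ratio rose to 0.73279 (0.675 to 0.771), so the gap narrowed and remained. The bound fixed in advance was set on the ratio itself, which lay below it, on the side against damage as the cause. Its interval spans that bound, however. Read by the interval, damage and a smaller RNA content cannot be told apart. In library 1 the ratio went from 0.841 to 0.962 (0.812 to 1.15). The design has 1 group, so no biological explanation was tested.

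Dissociation and immediate early genes were lower in LEC-like cells, and shallow or damaged LECs could give this. In cells of at least 2000 UMIs the median log2 fold change of the list was -1.87 (quartiles -2.35 to -1.39), below 0 in 20 of 20 members. The difference was thus also present in deeper cells. Deep cells weigh most in summed counts, so leaving out shallow ones could move this median little and cannot decide their part. Without scaling between classes the median of the list was -1.85 (-2.33 to -1.32). Leaving out the scaling moved the median of all genes by 0.10 log2, so this value followed from that shift and is no independent evidence. The shift itself is small beside the change of the list. No biological explanation was tested.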
